A study of Mus musculus with 9 samples.

How the data were processed

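The series measured binding of the glucocorticoid receptor (GR), a steroid hormone receptor that binds DNA when it carries cortisol or corticosterone, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Granulosa cells, the cells that surround the oocyte in the ovarian follicle, were collected from 21-day-old CBA x C57BL/6 F1 mice. The mice had received 5 IU of equine chorionic gonadotropin (eCG), which makes follicles grow as follicle-stimulating hormone (FSH) does, and 44 h later they either were killed (0 h) or received 5 IU of human chorionic gonadotropin (hCG), which stands in for the surge of luteinising hormone (LH), and were killed 6 h later. The files used here are 5 peak lists from wild-type cells, namely 2 GR libraries at 0 h, 2 GR libraries at 6 h and 1 library of acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, at 0 h. The other 4 of the 9 samples, which include GR libraries of a pair of progesterone receptor genotypes and pooled inputs, were not analysed here. No GR library came from mice killed at 6 h without hCG. An effect of hCG is therefore not separated from that of the later time after eCG or of the injection. The labels number the replicates and do not say whether they came from separate mice or pools, so p-values over libraries measure the spread between these libraries, which may be technical.

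Reads were aligned with Bowtie2 2.4.5 to build mm10 and peaks were called with MACS2, whose version is not given in the sources used here, per the submitters' processing notes. The authors made 1 list per library, so each library could be treated as a replicate. In the deposited GR lists each peak has a score, which is 10 times the −log10 p-value cut to a whole number, a fold enrichment (a ratio over the background the peak caller estimated), a −log10 p-value, a −log10 q-value and the position of its summit. The −log10 p-value of the weakest peak was 9.02, 9.00, 9.02 and 9.10 in the 4 GR lists, so a p-value limit of about 1e-09 had been applied before deposit. These values are the authors' own and describe or rank peaks within 1 list only. The deposited H3K27ac list gives positions without a score. Read depth and the control behind each list are not given in the sources used here, so a peak missing from a list shows only that it did not pass the authors' limit in that library, and a list from a deeper library can be longer with no difference in binding. Intervals below cover counting error only.

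Peaks on chromosomes 1 to 19, X and Y were kept. Peaks of the 4 GR lists that overlapped by 1 bp or more were merged into loci, and a library called a locus if a peak of that library lay in it. Loci only at 6 h were called in both 6 h libraries and in neither 0 h library, and loci only at 0 h the reverse. Overlap with H3K27ac also meant 1 bp or more. Chance levels came from 100 shuffles of each list within its chromosomes. Gene positions were taken from an NCBI RefSeq table of the assembly GRCm38.p6, which has the coordinates of mm10, for 21887 protein-coding genes. That table gives no strand, exons or sequence. The planned classes of location were therefore reduced to loci within 1 kb of either end of a protein-coding gene, other loci inside such a gene, and loci outside, and introns, exons and untranslated regions are not told apart. For the same reason, the planned window around transcription start sites became the gene span with 50 kb to each side, the nearest gene stands in for the nearest start site, and the planned search for GR response elements and other motifs was not made.

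Numbers per library were compared with exact permutation tests, whose smallest p with 2 against 2 libraries is 0.333. Shares of loci were compared with Fisher's exact test, two-sided, and loci are not replicates, so these tests describe the libraries at hand. Loci near the same gene are not independent either, so the p of a split by time near a list is too small where loci gather at few genes. Intervals of shares are 95% Wilson intervals. Before the data were examined, 15 gene lists with 265 entries (261 distinct genes, all found) were fixed, for the ovulatory response to LH, luteinisation and steroid synthesis, the preovulatory FSH response, the glucocorticoid response, glucocorticoid handling, inflammation and prostaglandins, the circadian clock, matrix and vessels, the cell cycle, AP-1 and early transcription factors, markers of theca, oocyte, leukocyte and endothelial cells, and housekeeping. For each class of loci, members with a locus in their window were set against all other protein-coding genes with Fisher's exact test, Benjamini-Hochberg adjusted over the 15 lists, and against 10000 random lists matched on the number of H3K27ac peaks in the window. The rule for named genes was also fixed in advance. It took the 10 loci of each class with the best mean rank by the authors' p-value, the list members with a locus of each class (the 4 with the locus nearest to a gene end when there were more than 4) and Nr3c1, the gene of GR. Other genes are named where said.

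The alternatives fixed in advance were the stronger part of each list (50%), equal numbers of peaks per library, a 50% overlap, merging across 500 bp, leaving out each library in turn, pairing by replicate number, a gene end distance of 3 kb, windows of 10 and 100 kb, and genes with an H3K27ac peak as the background. Joining peaks only where 2 overlap by 50%, windows around gene ends only, and leaving out loci inside genes were added after the data were seen. Merging and classing were tested on simulated lists with a detection rate of 85% per library. They recovered 51.8% of 5000 loci present in all 4 libraries (52.2% expected), 71.3% of 2515 loci present at 6 h (72.3% expected) and 72.6% of 700 loci present at 0 h (72.3% expected). Of the simulated loci called only at 0 h, 87.0% were truly absent at 6 h, against 95.8% for loci called only at 6 h, since missed peaks of shared loci also enter these classes. The simulation gave each locus the same independent detection rate in each library. In the data the second 6 h library alone missed 1830 loci and the first alone 58, so the simulated rates do not carry over to the data. The list test on those data, with 21887 genes, gave a Fisher's exact p of 1.9e-06 for a list of 25 genes of which 15 had been given a locus, and a p under 0.05 for 3.6% of 1000 random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.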

Results

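GR binding was mapped in mouse granulosa cells before hCG (0 h) and 6 h after it, the time at which the follicle prepares to release the oocyte and to turn into a corpus luteum. The GR lists held 10119 and 9728 peaks at 0 h and 14748 and 10588 peaks at 6 h, or 9923.5 ± 276 against 12668 ± 2942 (mean ± SD, n = 2 each). The difference of 2744.5 peaks was within the spread of the 6 h libraries and could not pass an exact permutation test (p = 0.333, the smallest possible). On chromosomes 1 to 19, X and Y the difference was 667 peaks without the first 6 h library and 4825 without the second. Median peak widths were 392 and 374 bp at 0 h and 393 and 322 bp at 6 h, and the median fold enrichments given by the authors were 7.34, 7.68, 7.89 and 6.89. The H3K27ac list, from 1 library at 0 h, held 37460 peaks with a median width of 637 bp.

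The first comparison asked which regions GR occupied before and after hCG. The 4 lists merged into 18584 loci. Of these, 2806 (15.1%) were called in both 6 h libraries and in neither 0 h library, 771 (4.15%) in both 0 h libraries and in neither 6 h library, and 5012 (26.97%) in all 4. The strongest locus only at 6 h lay inside Ano6, and the strongest loci in all 4 libraries lay in Zbtb16, Per1 and Kmt2a. Zbtb16, a transcription factor gene, and Per1, a core clock gene, are known to respond to glucocorticoids. Parting the same libraries by time gave 3577 loci private to 1 pair, and the other ways to part them gave 768 and 494. Libraries of the same time shared more of their loci (Jaccard index 0.669 at 0 h and 0.534 at 6 h) than libraries of different times (0.384 to 0.489). The mean difference was 0.168, and with 3 ways to part 4 libraries its exact permutation p was 0.333, the smallest possible. Shuffled lists gave on average 47.5 loci only at 6 h, 31.4 only at 0 h and 0 in all 4. The counts depended on the libraries and on list length. With 1 library alone standing for 6 h, the loci only at 6 h numbered 4320 (without the first 6 h library) or 5777 (without the second). The loci only at 0 h numbered 1667 without the first 0 h library, 1734 without the second and 2641 without the first 6 h library. Leaving out a library drops a condition of these classes, so a rise was fixed in advance and only its size is informative. With the 9726 strongest peaks of each library, 2064 loci were only at 6 h and 1432 only at 0 h. This cut shortened mainly the first 6 h list, from 14746 peaks, so a fall at 6 h and a rise at 0 h were largely set in advance. With the stronger 50% of each list, 1675, 469 and 2131 loci fell in the 3 classes.

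**Figure D1:**
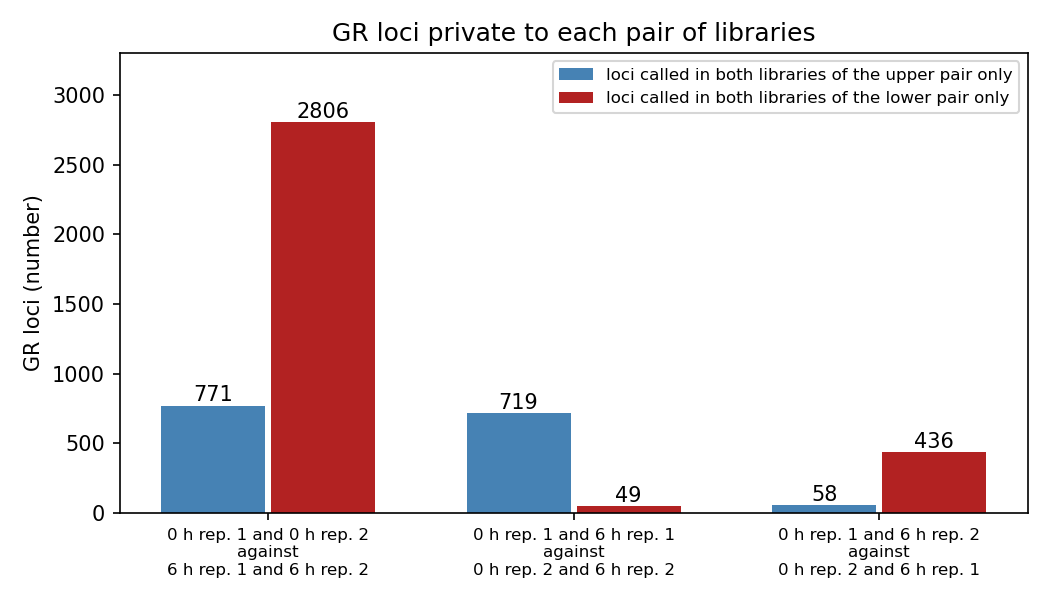
Number of GR loci (y axis) called in both libraries of 1 pair and in neither library of the other pair, for the 3 ways to part the 4 GR libraries into pairs (x axis, the pair named first in blue and the pair named last in red). The split by time gave 771 and 2806 loci, and each of the other splits gave at most 719 on either side.

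The second comparison set GR binding against chromatin that was already active before hCG. Loci in all 4 libraries lay almost wholly in H3K27ac peaks of 0 h, 98.4% of them (95% Wilson interval 98.0 to 98.7), as did 91.3% of the loci only at 0 h (89.1 to 93.1). Of the loci only at 6 h, 39.3% did (37.5 to 41.1). The difference from the loci in all 4 libraries was −59.1 percentage points (Fisher's exact p below 1e-300, the limit of the computation). The difference from the loci only at 0 h was −52.0 points (Fisher's exact p = 6.6e-163). Of the 10 strongest loci only at 6 h, those near Ano6, Spin1, Wbp1l, Ttc23, Pde1a, Arhgap31, Dtnb and Kmt2c lay outside H3K27ac peaks and those near Frmd5 and Kcnab1 inside. Peak by peak, 94.6% and 94.6% of the 0 h peaks and 77.9% and 70.7% of the 6 h peaks overlapped H3K27ac. The difference of the means was −20.3 percentage points (n = 2 each, exact permutation p = 0.333, the smallest possible). Shuffled peaks overlapped it in 1.81% to 1.89% of cases. H3K27ac was mapped in 1 library and at 0 h only, so the mark at 6 h was not analysed here.

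The classes also lay at different distances from genes. Of the loci in all 4 libraries, 76.6% (75.4 to 77.8) lay within 1 kb of an end of a protein-coding gene, where promoters are found. Of the loci only at 0 h, 31.8% (28.6 to 35.1) did, and of the loci only at 6 h, 9.19% (8.18 to 10.3). Against the loci in all 4 libraries, Fisher's exact p was below 1e-300 for 6 h and 2.6e-129 for 0 h. The difference for 6 h ranged from −66.9 to −53.8 percentage points with 1 library left out. The remaining loci only at 6 h were inside genes (52.8%) or outside (38.0%). Per library, 67.8% and 65.3% of the peaks at 0 h and 53.2% and 46.0% of those at 6 h were near a gene end. The gene table has 2 ends per gene and no strand, so start and end of a gene were not told apart.

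**Figure D2:**
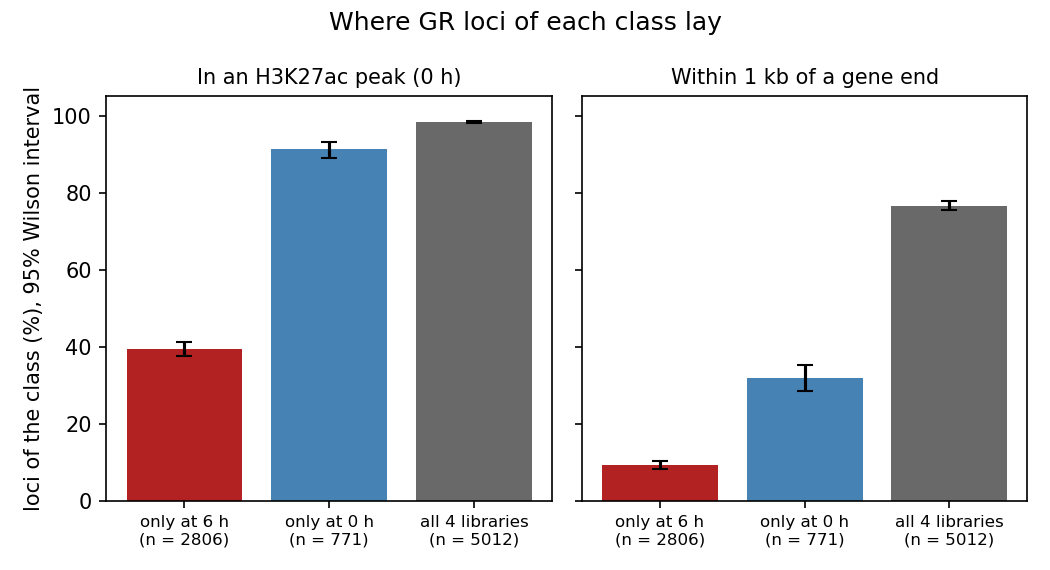
Share of GR loci (y axis, percent, with 95% Wilson intervals) that overlap an H3K27ac peak of the 0 h library (left) or lie within 1 kb of an end of a protein-coding gene (right), for loci only at 6 h, only at 0 h and in all 4 libraries (x axis). Loci only at 6 h have the lowest share in both panels, 39.3% and 9.19%.

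The next comparison asked which genes lay near loci called only at 6 h. Of the 25 genes of the ovulatory LH response, 16 had a locus only at 6 h within 50 kb, against 16.5% of other protein-coding genes (Fisher's exact adjusted p = 2.0e-06). Matched random lists had a mean of 4.66 such members (permutation p = 1e-04, the smallest these draws can give, adjusted p = 0.0015). The members with the nearest loci were Ptgs2, the inducible enzyme of prostaglandin synthesis, Tnfaip6, which helps to stabilise the matrix of the cumulus, Runx2, a transcription factor, and Rgs2, a regulator of G protein signalling. The Tnfaip6 locus (chromosome 2, 52037833 to 52038310 of mm10) overlapped a gene end and lay outside H3K27ac. Its fold enrichments were 16.5 and 14.6 in the 6 h libraries. The window of Tnfaip6 held 8 loci only at 6 h and none only at 0 h or in all 4 libraries. The Ptgs2 locus (chromosome 1, 150099901 to 150100208) also overlapped a gene end and was weaker, at 7.83 and 5.67. Pgr, Adamts1 and Vcan were chosen after their values were seen. Pgr, the progesterone receptor gene, had 1 locus only at 6 h (chromosome 9, 8867545 to 8867940), which lay 30960 bp outside the gene. Adamts1, a matrix protease gene, had 1, and Vcan, the gene of the matrix proteoglycan versican, had 11. The window of Vcan held 35 more loci called in other sets of libraries, all 35 of them overlapping the gene. Areg, Btc, Has2, Ptx3 and Plat, also named after their values were seen, had no locus of the 3 classes and 0 to 2 loci called in other sets of libraries. Near the list, 43 distinct loci were only at 6 h and 1 only at 0 h, near Zfp36 (odds ratio 11.98, Fisher's exact adjusted p = 0.0045 against all other loci of these classes). With loci inside genes left out, 15 were only at 6 h and 1 only at 0 h, and the split no longer passed (odds ratio 3.33, Fisher's exact p = 0.331). Of the 43 loci, 16 lay in H3K27ac peaks and 27 inside a gene of the list.

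Genes known to respond to glucocorticoids stood out in the same class. Of 24 members of that list, 12 had a locus only at 6 h (Fisher's exact adjusted p = 0.0012, adjusted p = 0.0125 against matched lists by permutation). Those with the nearest loci were Zbtb16, Mt2, a metallothionein, Ddit4, an inhibitor of mTOR signalling, and Glul, glutamine synthetase. The locus next to Mt2 (chromosome 8, 94171228 to 94171937) lay 681 bp from the gene and outside H3K27ac, with fold enrichments of 17.1 and 16.4. It also lay in the window of the neighbour Mt1 and so counted for both members. Matched lists draw genes independently, so the p-values of this list may be too small. The locus of Glul (chromosome 1, 153909465 to 153909972) overlapped a gene end, with 12.6 and 11.5. Loci in all 4 libraries lay near 18 of the 24 members, among them Per1, Dusp1, Klf9 and Mt1. Each of the 12 members with a locus only at 6 h also had a locus in all 4 libraries. For loci in both 6 h libraries whatever the 0 h call, also planned, the list had 18 of 24 members and did not pass. Its adjusted p was 0.083 by Fisher's exact test and 0.50 against matched lists by permutation. The ovulatory list passed there, with 20 of 25 (Fisher's exact adjusted p = 0.0218, permutation adjusted p = 0.0255). The loci near this list did not differ from other loci in their split by time, 23 only at 6 h and 3 only at 0 h (Fisher's exact adjusted p = 0.72).

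Another 4 lists had more members with a locus only at 6 h than other genes, and these calls depended on the setting. Matrix and vessels had 9 of 20, with Mmp19, Itga5 and a locus shared by the neighbours Col4a1 and Col4a2. Luteinisation and steroid synthesis had 9 of 20, with Star, which moves cholesterol into mitochondria, Cyp11a1, which cuts its side chain there, and its electron donors Fdx1 and Fdxr. AP-1 and early transcription factors had 8 of 20, with Fosb, Fosl1, Jund and Nr4a2. The circadian clock had 7 of 17, with Cry2, Bhlhe40, Npas2 and Nfil3. Their Fisher's exact adjusted p-values were 0.00996, 0.00996, 0.0319 and 0.0350, in this order. Matrix and vessels also stood apart from matched lists (permutation, adjusted p = 0.0075), and the other lists did not (adjusted p = 0.29, 0.12 and 0.31). The 9 matrix members include the neighbours Col4a1 and Col4a2. They also include Hapln1, named after its values were seen, whose 1 locus lay inside the nearby Vcan gene. Matched lists draw genes independently, so the p of the matrix list may be too small. None of these 4 lists passed Fisher's exact test with genes that have an H3K27ac peak as the background (adjusted p = 0.14, 0.11, 0.14 and 0.14, odds ratios 2.92, 3.07, 2.50 and 2.92). None passed it with loci inside genes left out (Fisher's exact adjusted p = 0.25, 0.80, 0.64 and 0.24). The odds ratios were 4.14, 4.14, 3.37 and 3.54 with all loci and 2.75, 0, 1.73 and 3.34 without those inside genes. Without the second 6 h library, the Fisher's exact adjusted p was 0.25 for matrix and vessels, 0.12 for luteinisation and 0.22 for the clock. Inflammation and prostaglandins did not pass (7 of 20, Fisher's exact adjusted p = 0.076), with Il1r1, Cxcl1, Ptgs1 and Cxcr4 nearest. Neither did housekeeping (5 of 15, with Rplp0, Ywhaz, Hprt and Actb nearest), the preovulatory FSH response (5 of 22, with Amh, Inhba, Amhr2 and Bmpr1b), the cell cycle (4 of 20, Ccne1, Pcna, Bub1 and Cdkn1b) and glucocorticoid handling (2 of 10, H6pd and Ncoa1). Markers of other cell types did not pass either. They had 3 of 14 members for leukocytes (Cd68, Itgam and Fcer1g), 2 of 13 for endothelial cells (Pecam1 and Cdh5), 1 of 14 for the oocyte (Zp3) and 1 of 11 for theca cells (Enpep).

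Loci called only at 0 h lay near genes of the preovulatory granulosa cell. Of the 22 genes of the FSH response, 13 had a locus only at 0 h within 50 kb, against 6.73% of other genes (Fisher's exact adjusted p = 2.6e-09). Matched lists had a mean of 5.02 such members (permutation p = 2e-04, adjusted p = 0.003). The members with the nearest loci were Inhbb, a subunit of inhibin and activin, Hsd17b1, an enzyme of oestradiol synthesis, Gja1, the gap junction protein connexin 43, and Fst, the activin antagonist follistatin. The Inhbb locus (chromosome 1, 119421988 to 119422612) overlapped a gene end, with fold enrichments of 6.68 and 8.90 in the 0 h libraries. Those of Hsd17b1 (5.31 and 6.11) and Gja1 (5.95 and 6.55) were weaker. The Fst locus (chromosome 13, 114458702 to 114458947) had 10.7 and 9.46. It lay beside a locus called in all 4 libraries (114459044 to 114459703, with 10.4, 9.03, 8.37 and 8.31), so it may be the edge of a site bound at both times. The same holds for the locus of Ccnd2 (chromosome 6, 127149805 to 127150296), a member named after its values were seen. It lay beside a locus called in all 4 libraries (127150368 to 127151165). Merging across 500 bp, which would join these loci, was not run for the lists. The next 5 genes were chosen after their values were seen. Inhba, the gene of another activin subunit, had 9 loci only at 0 h, and Cyp19a1, the aromatase gene, Foxl2 and Esr2 had 1 each beside loci in all 4 libraries. Fshr, the FSH receptor gene, had no locus of this class and 1 locus in all 4 libraries, with fold enrichments of 27.3, 27.8, 24.0 and 23.8. Near the list, 30 distinct loci were only at 0 h and 10 only at 6 h (odds ratio 0.088 for 6 h, Fisher's exact adjusted p = 8.6e-12), and each of the 30 lay in an H3K27ac peak. Of these 30 loci, 21 lay inside a gene of the list. With all loci inside genes left out, 3 members kept a locus (Inha, Inhbb and Foxl2, against 1.68% of other genes, Fisher's exact adjusted p = 0.0872). The loci left near the list, at these 3 genes, were 6 only at 0 h and 0 only at 6 h (Fisher's exact p = 3.3e-05 with loci taken as independent).

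Luteinisation and steroid synthesis also passed for loci only at 0 h, with 6 of 20 members (Fisher's exact adjusted p = 0.0123), and did not stand apart from matched lists (permutation, adjusted p = 0.64). Its nearest loci belonged to Hsd3b1, Lhcgr, the LH receptor gene, Nr5a1 and Por. The Fisher's exact adjusted p was 0.15 without the second 0 h library and 0.49 without the first 6 h library, and with loci inside genes left out no member had one. The other 13 lists had 0 to 3 members with such a locus and did not pass. Among those members were Ccna2, Mcm2 and Aurkb of the cell cycle, Zp1 and Gdf9 of the oocyte, Gapdh of housekeeping, and Hsd11b2 of glucocorticoid handling. Ptges and Hpgd of prostaglandins, Fkbp5 and Per1 of the glucocorticoid response, and Per1 again of the clock also had one. Single members of other lists were Zfp36, Angpt2, Nr4a1, Cd3e and Plvap.

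**Figure D3:**
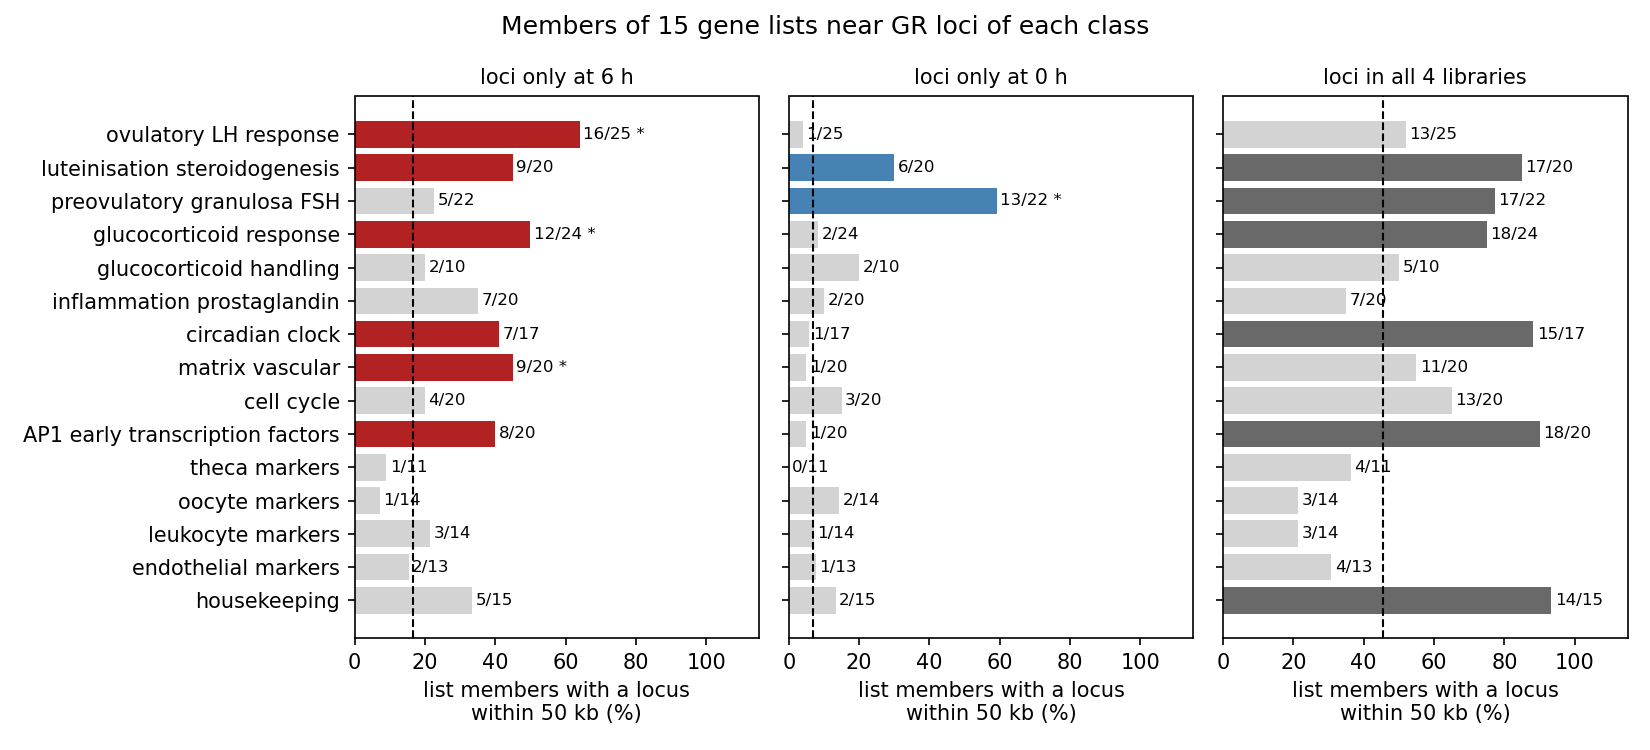
Share of the members of each of 15 gene lists (x axis, percent, with members with a locus over members beside each bar) that had a GR locus only at 6 h (left), only at 0 h (middle) or in all 4 libraries (right) in the gene or within 50 kb. Dashed lines give the share among other genes, bars in colour passed Fisher's exact test after adjustment and a star marks lists that also stood apart from matched random lists, which are the ovulatory, glucocorticoid response and matrix lists at 6 h and the preovulatory list at 0 h.

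Loci in all 4 libraries lay near 45.5% of the genes outside a list. They lay near 18 of 20 AP-1 and early transcription factors, among them Fos, Fosb, Fosl2 and Jun, and near 15 of 17 clock genes, among them Per1, Cry1, Cry2 and Nr1d2. Luteinisation had 17 of 20, with Scarb1, Hsd17b7 and Fdx1, and housekeeping had 14 of 15, with Gapdh, Hprt, Rplp0 and Ppia. The FSH response had 17 of 22, with Inha, Foxl2, Gja1 and Nppc, and the glucocorticoid response 18 of 24. These 6 lists passed Fisher's exact test (adjusted p from 0.00071 to 0.0104), and none stood apart from lists matched on H3K27ac (permutation, adjusted p from 0.057 to 0.90). The ovulatory list had 13 of 25, with Adamts1, Cebpb, Egr1 and Fosl2, and did not pass (Fisher's exact adjusted p = 0.64). Matrix and vessels (11 of 20, with Vegfa, Lamc1, Efnb2 and Plau) and the cell cycle (13 of 20, with Ccne1, Pcna, Cdc20 and Cdkn1b) did not pass. Inflammation (7 of 20, with Cxcr4, Rela, Il11 and Hpgd) and glucocorticoid handling (5 of 10, with Fkbp4, Ncoa1, Ncoa2 and Ncor1) did not pass. Marker lists did not pass. They had 4 of 11 for theca cells (Cyp17a1, Ptch1, Gli1 and Nr2f2), 4 of 13 for endothelial cells (Pecam1, Tie1, Egfl7 and Esam), 3 of 14 for the oocyte (Zp1, Zp3 and Gdf9) and 3 of 14 for leukocytes (Cd68, Csf1r and Fcer1g).

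Ranked by the authors' p-value, the first of the loci only at 6 h lay inside Ano6 (chromosome 15, 95914754 to 95915444), 60028 bp from the nearest gene end. Its fold enrichments were 39.97 and 46.1. It was followed by loci 3530 bp from Frmd5 (36.5 and 38.8), inside Kcnab1 (30.7 and 33.5) and 71028 bp from Spin1 (31.7 and 38.3). Among loci only at 0 h, the strongest lay 20102 bp from Btbd3 (chromosome 2, 138235958 to 138236481), with 12.1 and 18.9. The others were near Zwint, Rab12, Opn4, Wapl, Rpn1, Hpgd, Hmcn2, Defb42 and Pacc1. The median rank of a locus within the lists that called it, from 0 for the strongest to 100 for the weakest, was 64.5 for loci only at 0 h, 41.0 for loci only at 6 h and 35.3 for loci in all 4 libraries. The strongest locus in all 4 libraries lay inside Zbtb16 (chromosome 9, 48723119 to 48724170), with fold enrichments of 42.5, 43.2, 52.4 and 38.5. It was followed by a locus inside Per1 (chromosome 11, 69096007 to 69098024), with 42.6, 44.8, 47.6 and 30.9, and a locus at an end of Kmt2a (chromosome 9, 44881258 to 44881923), with 49.4, 57.97, 52.8 and 41.99. Another 2 of the 10 lay inside Zbtb16, and the rest lay in Klf13, Sphk2, Mrpl12, Cipc and Tbpl1. Nr3c1 itself (chromosome 18, 39410545 to 39519421) had 4 H3K27ac peaks and 0 GR loci in its window in any of the 4 libraries.

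**Figure D4:**
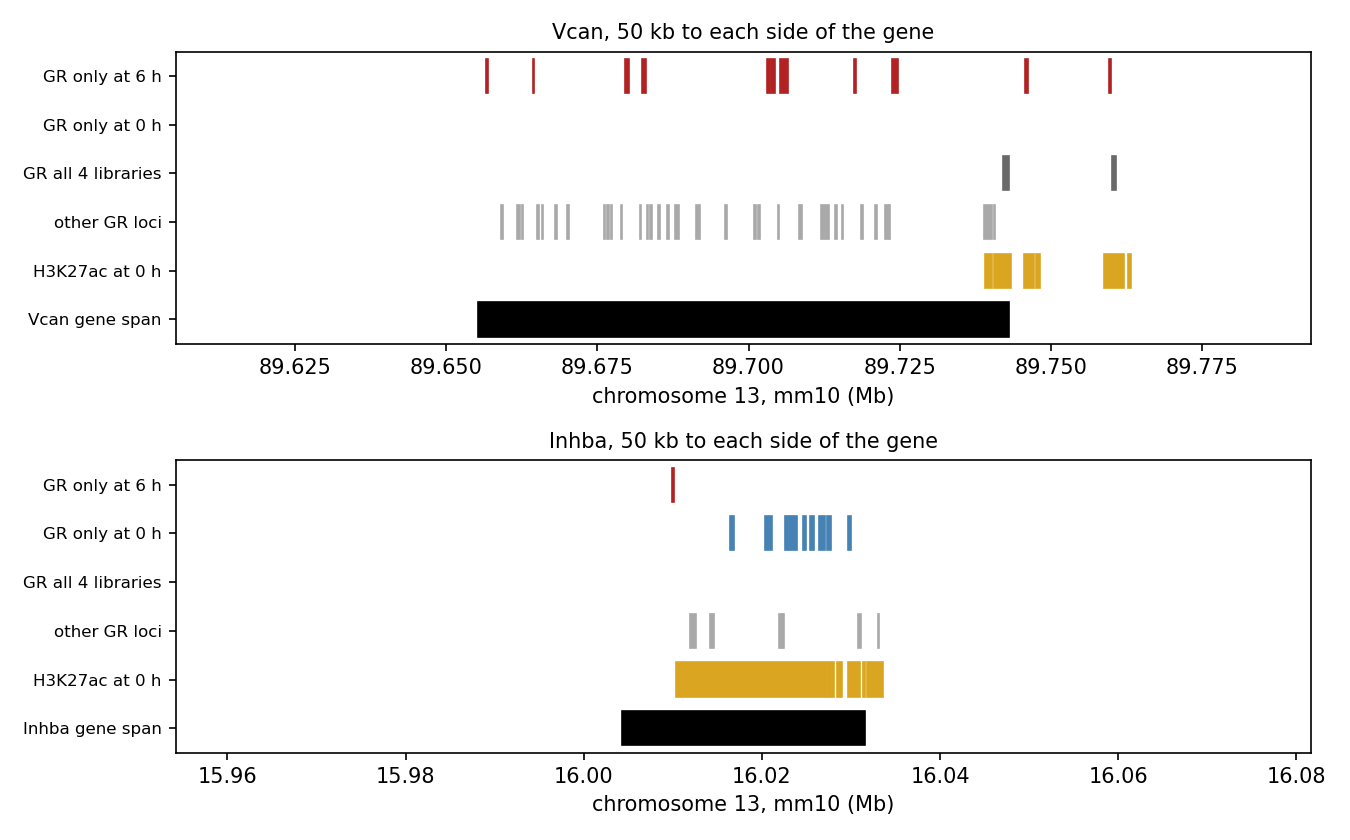
Maps of Vcan (upper) and Inhba (lower) with 50 kb to each side, the members of the ovulatory list and the FSH list with the most loci only at 6 h and only at 0 h (x axis, position on chromosome 13 of mm10 in Mb). Bars show, from the bottom, the gene span, H3K27ac peaks of 0 h, GR loci called in other sets of libraries, in all 4 libraries, only at 0 h and only at 6 h, with 11 loci only at 6 h at Vcan and 9 only at 0 h at Inhba.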

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

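The test on strong loci, the split by time of loci outside genes and the matched lists with window length were chosen after the results they bear on had been seen, and leaving out loci inside genes was added after the gene lists had been tested. The H3K27ac list held 7 peaks on contigs that belong to no chromosome used here, above the limit of 3 that a count of 0 allows. These peaks entered no comparison.

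Loci only at 6 h lay in H3K27ac peaks of 0 h far less often than loci in all 4 libraries. Wider shared loci, which meet a peak more easily, do not account for the gap, since it was −62.8 percentage points with each locus reduced to its summit. Nor does distance from promoters, since the gap was −59.9 points among loci over 1 kb from any gene end (36.3% against 96.2%), nor do weak peaks, since 37.6% of the strongest loci only at 6 h (904 loci, the best 25% of ranks) lay in H3K27ac. A hypothesis that these tests leave open is that hCG let GR reach regions that were not acetylated before it. The design does not separate hCG from the later time after eCG. Acetylation at 6 h was not analysed here, so whether the regions gained the mark was not tested.

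The ovulatory genes had loci only at 6 h more often than other genes. The number of H3K27ac peaks at 0 h and gene length do not account for it, since 100% of 10000 random lists matched on that number and window length held fewer such members, though the width of these peaks was not matched. Nor does the length of the 6 h lists, since the adjusted p was 4.5e-06 with equal numbers of peaks (1.7e-07 to 4.0e-04 over the 12 alternatives run for lists). Signal that runs along the bodies of transcribed genes may add loci at Vcan, but 10 of 25 members had a locus with all loci inside genes left out (Fisher's exact adjusted p = 1.3e-05), although the split of those loci by time did not pass (15 only at 6 h, 1 only at 0 h, Fisher's exact p = 0.331). Chromatin or transcription active at 6 h was not measured here. It stays open beside an effect of hCG, or of the later time, on GR binding near these genes.

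The preovulatory genes had loci only at 0 h more often than other genes. The number of H3K27ac peaks and gene length were argued against, since 100% of lists matched on them held fewer such members. The width of H3K27ac peaks was not matched. It was larger for peaks with loci only at 0 h (median 1624 bp) than for those with loci in all 4 libraries (1383 bp), so active chromatin is not excluded. The second 6 h library alone was argued against (Fisher's exact adjusted p = 6.2e-09 with only the first standing for 6 h). Weak 0 h peaks did not make up the whole pattern. Loci in the stronger 50% of both 0 h lists and in neither full 6 h list, 145 of 771, lay near 5 of 22 members (Fisher's exact adjusted p = 4.6e-05). Signal at 6 h just under the authors' limit cannot be seen in peak lists and was not tested. Signal along the bodies of active genes met the outcome set for it before the test, an adjusted p of 0.05 or more, since the Fisher's exact adjusted p was 0.0872 with loci inside genes left out. The call ended with 247 loci left of 771 and 3 of 22 members, and the odds ratio, compared only after that p was seen, was 9.25 (95% interval 1.74 to 31.6) against 20.01 (7.90 to 53.1). The 6 loci left near the list were all only at 0 h (Fisher's exact p = 3.3e-05 with loci taken as independent). But they lie at 3 genes and are too few to decide. Such a signal may thus make up part of the pattern. An effect of hCG, or of the later time, on GR binding is not separated from it.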

How the results depend on the processing

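For the main comparisons, 65 of 85 values kept their direction and call, or for counts stayed within 1.5 times the main value, 20 counts moved further and 0 reversed. The peaks per library (667 to 4825), the Jaccard index and the H3K27ac share per library could not pass in any setting, so only their direction was tested. Loci only at 6 h numbered 1675 with the stronger 50% of each list and 3153 to 5777 with 1 library left out, and loci only at 0 h numbered 469, and 831 to 2641. The rises with 1 library left out were fixed in direction, since a condition of the class is dropped. With equal numbers of peaks, 1432 loci were only at 0 h, a rise largely set in advance by shortening the first 6 h list. Loci in all 4 libraries numbered 2131 with the stronger 50%. The 2641 loci were found without the first 6 h library, and in the main analysis the second 6 h library alone missed 1830 loci. Replicate differences in calls at 0 h and 6 h were hardly correlated (r = 0.036 over 18584 loci), which cannot show that libraries were unpaired. Libraries of different times shared slightly more loci with the same replicate number (Jaccard index 0.489 and 0.389) than with different numbers (0.470 and 0.384). A replicate block on these numbers gave 5576.5 and 2861 loci for 6 h and 0 h. It gave a difference in H3K27ac share of −20.3 points (exact sign-flip p = 0.5, 2 pairs). It was run for no other result. Of the 15 lists, 6 passed for loci only at 6 h in the main analysis, 3 with windows of 100 kb and 2 with genes with an H3K27ac peak as background. For loci only at 0 h, 2 of the 15 passed in the main analysis, 1 with the stronger 50%, equal numbers, 100 kb windows or the H3K27ac background, 0 with loci inside genes left out, and 1 to 4 with 1 library left out. The cause was not tested. For single lists, 68 of 96 values stayed on the same side of the threshold, 25 lost the call and 3 reversed. The reversed values were all of luteinisation, which had 1 member with a locus only at 0 h with the stronger 50%, and 0 members at either time with loci inside genes left out. The ovulatory list and the glucocorticoid response passed at 6 h under the 12 alternatives run for lists (largest adjusted p 4.0e-04 and 0.0458), and the FSH list at 0 h under all of these but the one without loci inside genes (0.0872). Merging across 500 bp was run for locus counts only. A 50% overlap of a peak with its own locus moves no count, since peaks lie wholly in their loci, so a 50% rule for joining peaks was added instead. Motif alternatives were not run, since no sequence was used here. Leaving out loci inside genes, joining by 50%, windows around gene ends and all alternatives for lists at 0 h were chosen after seeing the data. Depth is unknown, so loci absent from a list were not detectable at the authors' limit rather than absent.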

Other observations

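The tests on neighbouring loci and on housekeeping genes, and the genes named here, were chosen after their values were seen. Loci only at 6 h gathered at several genes outside the lists. Gramd1b, which encodes a carrier of cholesterol between membranes, had 31 of them in the gene and 50 kb to each side (chromosome 9, gene at 40293233 to 40533614), beside 3 loci in all 4 libraries and none only at 0 h. The window of its neighbour Scn3b shared 16 of the 31, Vmp1 had 11, and Ephx2, Chrna2 and Adam2, which lie next to one another on chromosome 14, shared the same 12. Among loci only at 0 h, Inhba had the most with 9, followed by Greb1, a gene known to respond to oestrogen, with 7 beside 14 loci in all 4 libraries and 5 only at 6 h. The H3K27ac peaks that held loci only at 0 h had a median width of 1624 bp, against 1383 bp for those with loci in all 4 libraries, 872 bp for those with loci only at 6 h and 469 bp for the 23932 without a GR locus.

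A hypothesis from these genes is that regions gained or lost GR loci together. Of the loci only at 6 h, 36.0% had another of the class within 25 kb, against a mean of 31.8% and a highest value of 35.1% in 1000 draws from the loci of both 6 h libraries with the same share near gene ends (permutation p = 0.001, the smallest possible). For loci only at 0 h the share was 14.8%, against a mean of 9.50% and a highest value of 13.7% (permutation p = 0.001). Both shares go with the hypothesis, and the excess of 6 h loci over these draws is small. The genes that prompted the hypothesis were among the loci tested, and no draw was made without them, so the test is no independent support. The loci drawn from also included the class itself, so the size of the excess cannot be read from these draws. Signal along active gene bodies, as weighed for the preovulatory list, would give the same excess and was not separated from it here.

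The window with the most loci in all 4 libraries was that of Greb1 (14), followed by that of its neighbour Ntsr2 (10). Windows with 9 were those of Phf20 and Rbm39 on chromosome 2 and of histone genes, among which H2ac20, H2ac21 and H2bc21 on chromosome 3 and H2ac7, H2bc7 and H2bc8 on chromosome 13 each shared the same 9 within their group. A candidate explanation is that loci in all 4 libraries follow active chromatin in general. Housekeeping genes had such loci at 14 of 15 members, and 92.4% of random lists matched on H3K27ac peaks and window length held fewer. This list did not stand apart from genes with as many H3K27ac peaks and as long, but at 14 of 15 it had little room to do so. In the same test fewer members were held by 99.4% of lists for AP-1 and early transcription factors and 97.1% for the clock. The shares were 94.0% for the glucocorticoid response, 89.8% for luteinisation and 46.6% for the FSH response, all without adjustment. The explanation may thus not cover the early transcription factors. Whether these loci hold a GR response element was not tested.

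The 6 h libraries differed in which shared regions they called. The second 6 h library alone missed 1830 loci that the other libraries all called, of which 76.1% lay near a gene end, and the first alone missed 58. Of the loci called in a single library, 2912 came from the first 6 h library, 35.7% of them near a gene end, and 1398 from the second, 7.15% of them near a gene end. All 18 GR peaks on chromosome Y lay between 90740062 and 90812479, at the far end of the chromosome.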
